A study of Zea mays with 18 samples.

How the data were processed

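RNA was measured in the maize inbred B73 in the unfertilized central cell, in endosperm collected on each of the first 4 days after pollination (DAP), and in embryos of 4 DAP, with 3 libraries in each of the 6 groups, 18 in all. Per the labels, tissue was taken by laser capture from kernels of greenhouse ears that were either left unfertilized or self-pollinated. Each replicate pooled sections of several kernels from a single ear. RNA was extracted with the PicoPure kit, copied with oligo(dT) and random primers, amplified with the Nugen Ovation kit and sequenced in paired ends on an Illumina HiSeq. The labels also say that RNA of the 0 to 2 DAP samples and of the embryo was quantified differently from that of the 3 and 4 DAP endosperm, by the height of the 18S band, because of a carried-over product. That difference coincides with the stages. Because the RNA was amplified, the reads are not independent molecules, and the intervals and lower bounds given here cover counting error only.

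The deposited table holds 1 normalised signal value per gene and library, in CPM, for 38300 genes. Every value in every library was a whole multiple of 1 step, within 0.001 reads, so whole read counts could be recovered. The column totals ran from 850346.3 to 1241737.6 with a geometric mean of 1000000.0, as normalization factors of the edgeR type give. The recovered reads ran from 7688120 in replicate 1 at 1 DAP to 124078873 in replicate 1 at 2 DAP. The labels name Trimmomatic, TopHat2 2.0.9, bedtools 2.17.0, edgeR and the genome build B73 RefGen_v3, without saying what each did. The strandedness of the counting and its treatment of reads shared by near-identical genes are not given in the sources used here. Reads of an overlapping gene on the opposite strand, or of a close copy, could therefore be counted for a gene.

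Gene names came from a reference table of a later B73 assembly, joined by gene identifier. Of the 38300 genes, 14444 (37.7%) matched an entry, 1972 had a gene name beyond an identifier, and 455 matched more than 1 entry. Positions were not used, since the builds differ. Some names cover more than 1 gene model: meg2 and wox13A each name 2 models and H4C13 names 3, while esr1 and esr2 share several synonyms. AGP2 (GRMZM2G027955) and Agp2 (GRMZM2G106213), told apart only by case, are different models of the starch list. A gene identifier is given where the name alone is not enough. Tests for gene length or GC content were not made, since less than 80% of the genes had a value.

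The values were put on the scale log2(CPM + 1). Genes with at least 1 CPM in at least 3 libraries were tested, which left 31783. A linear model with 1 mean per group was fitted to all 18 libraries with limma 3.58.1 (trended variance) in R 4.3.3, and p-values were adjusted by the Benjamini-Hochberg method within each comparison. A gene was called at an adjusted p below 0.05. The pseudocount of 1 understates the change of genes near it. The comparisons were each endosperm stage against the one before it, 4 DAP against 0 DAP, and the embryo against the endosperm at 4 DAP. An F test covered the 5 endosperm stages, and a gene was called stage-enriched where it was higher at 1 stage than at each of the other 4. All tests of single genes were two-sided.

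The comparisons, the tests, the thresholds, the themes of the gene lists and the rule for named genes were fixed before the data were examined. The exact members of the lists were matched by name patterns written after the names in the reference table were seen and before any expression test. Of 42 lists planned, those of B3-domain genes and of the proteasome had no usable names, and lists of endoplasmic reticulum (ER) chaperones and of defence genes took their place, so that 42 were tested. They cover mitotic regulators, G1/S regulators, DNA replication, histones, kinesins and phragmoplast proteins, tubulins and actins, and cell wall enzymes. Endosperm and embryo lists cover the basal transfer layer, the embryo-surrounding region, the aleurone, starch synthesis, storage proteins, sugar transport, small secreted peptides, Polycomb and imprinted genes, embryo regulators and genes of the egg cell, synergids and embryo sac. Hormone lists cover auxin, cytokinin, gibberellin, abscisic acid and ethylene. Regulator lists cover MADS-box, WRKY, MYB, NAC, bZIP, heat stress factors, NF-Y, homeobox and AP2/ERF genes and DNA methylation with small RNA genes. The remaining lists cover photosynthesis, nucellus and maternal tissue, cell death, ribosomal proteins, translation factors, heat shock proteins, glycolysis, fatty acids, ER chaperones and defence. Lists share members: the transfer-layer, embryo-surrounding and embryo-sac peptides also belong to the small secreted peptides, MEG1 to the Polycomb and imprinted list, and EBE-1 and EBE-2 to the embryo-sac list. The embryo regulators wox9B, wox9C and wox13A also belong to the homeobox list, and the transfer-layer gene mn1 to the sugar transport list. The gene model GRMZM2G039942, named ae1, was removed from the starch list after its values were seen, because a different entry carries ae1 together with the name of the branching enzyme. It is uncertain whether GRMZM2G113203, named MRP1 and mrpa1, is the transfer-cell regulator of that name.

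Lists were tested with camera at a preset correlation between genes of 0.01, adjusted over all 252 tests, and again with an estimated correlation. Camera compares the members of a list with the other genes. The alternative test fry asks instead whether the members move one way on balance, so its p answers another question. In no list that passed did the median and the mean differ in sign. Named genes had an adjusted p below 0.05, a mean of at least 10 CPM in the higher group, and 3 libraries all above the other 3. They are the 5 largest changes in each direction with a gene name and up to 3 members of each of the 6 lists with the smallest camera p. The rule also covered the members of the transfer-layer, embryo-surrounding, Polycomb and embryo lists, whatever their result. Values are given here for only some of those members. Where a count of 5 or fewer members of a list is given, members outside this rule are named too, which was decided after their values were seen. A fold against a group with 0 reads is a lower bound that assumes 3 reads over the group. With 1 to 3 reads the ratio has its 95% counting interval. These bounds and ratios use the reads pooled over the libraries of a group, while all other folds are ratios of mean CPM. List medians are also given with such genes at these values.

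The replicate number was checked as a possible pairing of the samples. Deviations from the group means were correlated above 0.1 between same-numbered libraries of different groups in 18 of 18 tests (0.15 to 0.696), and most strongly between same numbers in 16 of 18. The 3 deviations of a group sum to 0, so a shift shared by the replicate 1 libraries alone also raises the correlations of replicates 2 and 3. The 18 tests are therefore not independent. For replicate 1 the correlations were 0.481 to 0.696. Replicate 2 was at 0.352 against 0.36 with another number (4 against 3 DAP) and 0.15 against 0.362 (4 against 0 DAP). A shift shared by the replicate 1 libraries is thus shown, but not a pairing of all 3 numbers. The main fit, fixed in advance, leaves the number out, and its p-values ignore such a shift. Values from a fit with the replicate number as a block are given beside the counts. The labels do not say whether the endosperm and embryo of 1 number came from the same ear.

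The alternatives fixed in advance were pseudocounts of 0.25 and 5, no filter and a filter of 5 CPM, quantile normalization, TMM factors and median-of-ratios factors on the CPM values, a replicate block, array weights, a fit of the compared groups alone, a 2-fold minimum, edgeR 4.0.16 and DESeq2 1.42.0 on the recovered reads, an estimated correlation or fry for the lists, and leaving out each library in turn. Fits without the 2 shallowest libraries, without all replicate 1 libraries, and by edgeR with a replicate block were added after the data were seen. None of these scalings moved the median log2 change of all genes by 0.1 or more in any comparison. The main model was tested on simulated counts with the spread of these libraries. In each comparison 100 genes changed 2-fold and 100 changed 4-fold, all with a mean of 5 CPM or more. The model found 53% to 75% of 4-fold changes and 1% to 9% of 2-fold changes, with 1 to 4 false calls among 30617 to 30657 genes. No replicate effect was simulated, and fewer genes changed than were called in these data (792 to 11823). These shares and false calls therefore need not hold for the comparisons made here. Tables were handled with Python 3.11.15, pandas 2.3.3 and numpy 2.4.6, and plots were drawn with matplotlib 3.10.9.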

Results

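The series addressed which regulatory programs accompany proliferation and differentiation in the earliest maize endosperm. Each group had 3 libraries: the central cell before pollination (0 DAP), the endosperm on each of the next 4 days, and whole embryos of 4 DAP. The reads recovered for replicates 1, 2 and 3 were 76074658, 78713950 and 44250242 at 0 DAP, 7688120, 63765568 and 54000646 at 1 DAP and 124078873, 81035626 and 109432029 at 2 DAP. They were 62638705, 42634068 and 99508504 at 3 DAP, 99184532, 67350539 and 76289746 in the endosperm at 4 DAP and 9572961, 73813889 and 47136879 in the embryo. The most abundant gene of each library took 1.03% to 5.19% of its reads. The lowest Pearson r between replicates of 1 group was 0.925, over genes, which are not independent replicates. Replicate 1 at 3 DAP was closer to replicate 1 at 2 DAP (0.958) than to its own group (mean 0.9503). Replicates 2 and 3 at 3 DAP reached 0.9715 and 0.9732 with another group, above the means within their group (0.967 and 0.9673). All libraries but replicate 1 at 3 DAP were closest to a library of their own group. Values are mean CPM ± SD over 3 libraries. On principal components of the log2 values, the first 3 components held 32.4%, 22.3% and 12.1% of the variance.

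**Figure D1:**
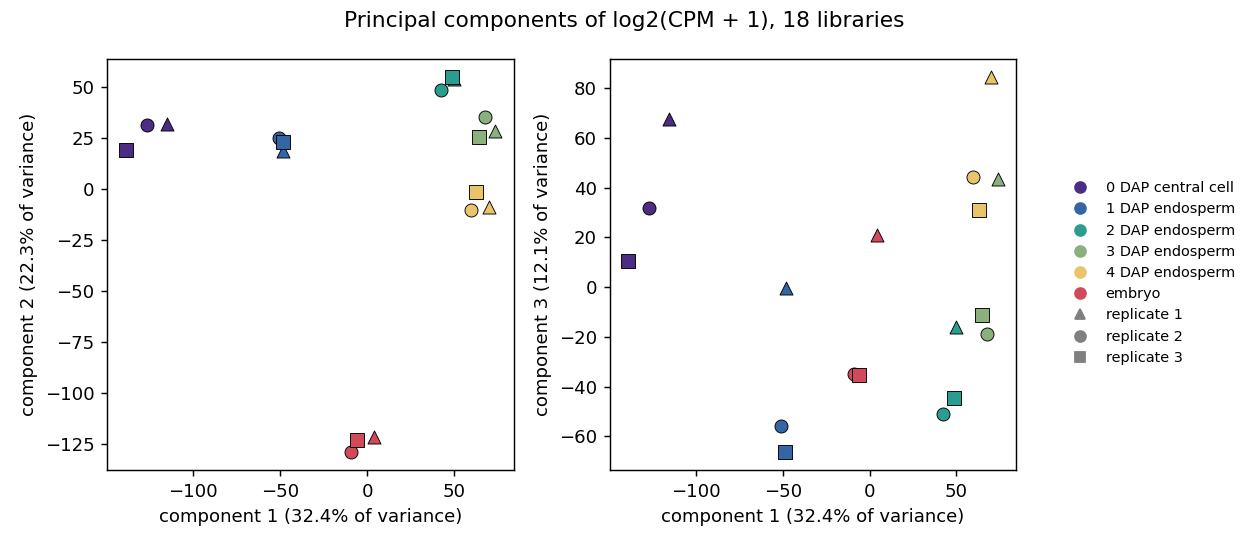
Principal components of log2(CPM + 1) for the 18 libraries, component 1 (32.4% of the variance) against component 2 (22.3%) and against component 3 (12.1%), colour for the group and marker shape for the replicate number. Each point is 1 library, and the 6 groups of 3 can be followed in both panels.

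The first day after pollination, 1 DAP against 0 DAP, compares young endosperm with the central cell. By camera, lists of cell-division genes rose and the embryo-sac list fell, but none of these passed with an estimated correlation (adjusted p = 0.252 to 0.389). The cyclin cyc3 (GRMZM2G073671) rose from 1.74 ± 0.251 to 145.4 ± 20.9 CPM (SD, n = 3), and the cyclin cyc1 (GRMZM2G034647) from 1.09 ± 0.852 to 85.4 ± 33.4 CPM. Yucca3 (GRMZM2G107761), a flavin monooxygenase of auxin synthesis, rose 92.9-fold to 889 CPM, and the DNA methyltransferase met5 (GRMZM2G005310) rose 35.6-fold to 283 CPM. The embryo-sac peptide genes es4, es2 and es1 fell from 154, 106 and 86.7 CPM to 9.0, 4.81 and 6.36 CPM. The gibberellin-synthesis gene d3 (GRMZM2G093195) fell 99.97-fold, from 282 ± 172 to 2.82 ± 0.610 CPM, and cystatin8 fell 37.6-fold. Of 12 histone genes, 11 rose and 0 fell, the same counts as when adjusted over the list alone, with a median log2 change of 2.72 (camera adjusted p = 1.2e-07, but adjusted p = 0.351 with an estimated correlation). H3C2 rose 16.9-fold, and the H4C13 models GRMZM2G084195 and GRMZM2G149178, which may share reads, rose 16.1-fold and 12.04-fold. Of 14 mitotic regulators, 9 rose, among them mad2, and 1 fell, the cenH3 model GRMZM2G157596, from 52.7 to 26.5 CPM (10 and 1 adjusted over the list alone; camera adjusted p = 2.42e-05, adjusted p = 0.389 with an estimated correlation). Of 14 kinesins and phragmoplast proteins, 7 rose (KIN13 7.84-fold, KIN8 6.06-fold, kin11 5.27-fold) and 2 fell, kin1 and ktn2 (9 and 2 adjusted over the list alone; camera adjusted p = 0.00042, adjusted p = 0.252 with an estimated correlation). Of 17 replication genes, 7 rose, with pcna2 at 156 against 48.2 CPM and RNRS1 and RNRS3 12.5-fold higher (8 adjusted over the list alone; camera adjusted p = 0.00126, adjusted p = 0.368 with an estimated correlation). By edgeR the falls of the cenH3 model (adjusted p = 0.0627), kin1 (0.0994) and ktn2 (0.262) were not called, nor were those of kin1 (0.233) and ktn2 (0.271) by DESeq2.

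Glycolysis, starch and embryo-sac lists fell over the same day by camera, though not with an estimated correlation (adjusted p = 0.252 to 0.268). Of 17 glycolytic genes, 9 fell, with GPC1 at 390 ± 66.9 against 1147 ± 438 CPM (SD, n = 3), and 14 fell adjusted over the list alone (camera adjusted p = 3.31e-05, adjusted p = 0.268 with an estimated correlation). Of 7 embryo-sac genes, 6 fell by either adjustment, and the median log2 change was -1.59, or -3.001 with genes near 0 at their bounds (camera adjusted p = 3.64e-05, adjusted p = 0.252 with an estimated correlation). Of 21 starch genes, 9 fell (10 adjusted over the list alone; camera adjusted p = 0.0043, adjusted p = 0.252 with an estimated correlation). Of 4 gibberellin genes, 3 fell by either adjustment: d3, CPPS2 and an1 (camera adjusted p = 0.00213, adjusted p = 0.119 with an estimated correlation). Of 11 WRKY genes, 4 rose (5 adjusted over the list alone): WRKY109 (GRMZM5G880069), WRKY (GRMZM2G125653), WRKY95 and WRKY116 (camera adjusted p = 0.0169, adjusted p = 0.252 with an estimated correlation). Of 30 bZIP genes, 11 rose and 1, bZip37, fell by either adjustment (camera adjusted p = 0.0309, adjusted p = 0.331 with an estimated correlation). The falls of an1 and bZip37 were not called by edgeR (adjusted p = 0.156 and 0.113) or DESeq2 (0.452 and 0.0625). With the replicate block this list no longer passed (adjusted p = 0.0539), nor without all replicate 1 libraries (0.0746), and its adjusted p over all alternatives ran from 0.00277 to 0.331. Of 39 ribosomal genes, rpl10 and rpl19 rose and arpp2b fell, and the list passed at camera adjusted p = 0.0272 (adjusted p = 0.805 with an estimated correlation). DESeq2 called 4 higher, and with the replicate block 19 were. The list did not pass without replicate 1 at 0 DAP (adjusted p = 0.295), without replicate 2 at 1 DAP (0.132) or without replicate 3 at 1 DAP (0.302), nor by fry (0.437), which asks whether the members move one way and not whether they differ from other genes, and its adjusted p ran from 1.85e-06 to 0.805 over all alternatives. Across the groups, 35 of the 39 ribosomal genes were lower in the replicate 1 libraries than in the others, with a median log2 difference of -1.07. The same held for 8 of 12 histone, 8 of 14 mitotic, 10 of 17 glycolytic, 8 of 12 nucellus, 7 of 12 fatty acid, 5 of 9 sugar transport, 7 of 13 translation, 10 of 20 tubulin and actin, 2 of 4 gibberellin and 14 of 29 defence genes. Smaller shares were lower in other lists, such as 13 of 33 cell wall, 8 of 20 abscisic acid, 9 of 28 MADS-box, 3 of 7 embryo-sac and 2 of 5 embryo-surrounding genes. Among all 31783 genes, 6802 were lower and 5434 higher in the replicate 1 libraries. In all, 7276 of 31783 genes were called by limma, 3285 higher and 3991 lower, and the libraries of the 2 stages did not overlap in 34.1% of genes, where chance gives 10%. With the replicate block 10839 genes were called. Of the called genes 45.1% were higher, but 56.4% were by edgeR. The 11 lists that passed had adjusted p from 0.119 to 0.805 with an estimated correlation, so none held there.

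From 1 to 2 DAP, by camera, the ribosomal and translation lists rose while the cell wall, starch, defence and MADS-box lists fell, but none of the 6 passed with an estimated correlation (adjusted p = 0.166 to 0.654). Yucca3 rose further, from 889 ± 151 to 7549 ± 2990 CPM (SD, n = 3), and Yucca6 (GRMZM2G019515) rose 69.4-fold to 45.9 CPM. The methyltransferase comt (GRMZM5G814904), cystatin8 and WRKY1 (GRMZM2G018487) rose 65.7-fold, 35.2-fold and 26.6-fold. The potassium transporter HAK5 (GRMZM2G084779) fell 38.9-fold, NIP1-1 162.5-fold, psiP 98.7-fold, AGA2 28.2-fold, and HRGP (GRMZM2G168651), a hydroxyproline-rich cell wall protein, 20.7-fold to 8.77 CPM. The Polycomb gene fie1 (GRMZM2G118205) rose from 18.2 ± 8.36 to 120 ± 5.05 CPM, after 0.242 CPM at 0 DAP, and mez1, nfc101, nfc102 and nfc103 rose with it.

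Of 39 ribosomal genes, 18 rose and 0 fell between 1 and 2 DAP (23 and 1 adjusted over the list alone), with a median log2 change of 1.28 (camera adjusted p = 1.53e-08, adjusted p = 0.654 with an estimated correlation). With the replicate block 33 rose and 1 fell. Among them rpl30 rose from 119 ± 68.7 to 480 ± 164 CPM (SD, n = 3), and RPL27A rose 4.01-fold. The same list differed between replicates: 35 of its 39 genes were lower in the replicate 1 libraries. Of 13 translation factors 9 rose (9 and 1 lower adjusted over the list alone), among them elfa2, elfa3 and tif5A (camera adjusted p = 0.000512, adjusted p = 0.549 with an estimated correlation, and 0.179 after quantile normalization, with a lowest value of 4.77e-05 over all alternatives). After quantile normalization elfa3 (adjusted p = 0.0971) and tif5A (0.0548) were not called, nor was elfa3 with the compared groups alone (0.0594). Their log2 changes were 0.61 and 1.03 after quantile normalization, against 1.23 and 1.58 in the main fit. Over all alternatives the adjusted p of elfa3 began at 4.82e-05 and that of tif5A at 8.42e-07. Without replicate 1 at 1 DAP the calls of rpl30 and tif5A were lost (adjusted p = 0.0513 and 0.0537). Their log2 changes were then 1.53 and 1.17, against 2.18 and 1.58 with all libraries. Of 33 cell wall genes 12 fell, including expA4 8.72-fold, expB6 9.16-fold and CesA-1 2.51-fold, and 1, expB7, rose (15 and 2 adjusted over the list alone; camera adjusted p = 3.49e-05, adjusted p = 0.304 with an estimated correlation). Of 21 starch genes 11 fell, including sus1 from 108 to 8.21 CPM, AGP2 (GRMZM2G027955) and sh1, and 1, iso2, rose. Adjusted over the list alone the counts were 12 and 1 (camera adjusted p = 0.000727, adjusted p = 0.166 with an estimated correlation). Of 29 defence genes 10 fell, including cystatin6 and GST3, and 2 rose, bx8 and cystatin8, by either adjustment (camera adjusted p = 0.000472, adjusted p = 0.559 with an estimated correlation). Of 28 MADS-box genes 10 fell, including zmm27 3.77-fold, and 1, MADS42, rose (13 and 1 adjusted over the list alone; camera adjusted p = 0.00257, adjusted p = 0.559 with an estimated correlation). The calls of zmm7 and MADS18 on this list each failed without 1 of several libraries: zmm7 without replicate 3 at 1 DAP (adjusted p = 0.0584) or replicate 1 at 2 DAP (0.0702), and MADS18 without replicate 2 or 3 at 1 DAP (0.0648, 0.108) or replicate 1 or 3 at 2 DAP (0.0595, 0.112). MADS18 was also not called by edgeR (0.108, or 0.0615 with a replicate block), by DESeq2 (0.0515) or with a pseudocount of 0.25 (0.0828), and its lowest value over all alternatives was 0.00322. The rises of expB7 (0.0603) and bx8 (0.0614) were not called by edgeR, nor that of expB7 by DESeq2 (0.0583).

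The auxin, abscisic acid, bZIP, tubulin and small peptide lists also fell from 1 to 2 DAP by camera, and again none passed with an estimated correlation (adjusted p = 0.328 to 0.773). Of 40 auxin genes 12 fell and 3 rose, Yucca3, Yucca6 and baf1 (13 and 3 adjusted over the list alone; camera adjusted p = 0.0211, adjusted p = 0.559 with an estimated correlation), while ARF13 fell from 216 to 45.9 CPM. Of 20 small peptide genes 5 fell by either adjustment: es1, es2, es4, PLTP and plt2 (camera adjusted p = 0.0186, adjusted p = 0.695 with an estimated correlation). Of 20 abscisic acid genes 6 fell (10 adjusted over the list alone) and PYL8 rose (camera adjusted p = 0.0193, adjusted p = 0.461 with an estimated correlation), though PYL8 was not called by edgeR (0.128) or DESeq2 (0.104), and the 6 became 10 by edgeR, 11 by DESeq2 and 10 with the replicate block. Of 30 bZIP genes 8 fell and bZIP103 rose, and of 20 tubulin and actin genes 6 fell, these 2 lists by either adjustment (camera adjusted p = 0.0291 and 0.04305, adjusted p = 0.328 and 0.773 with an estimated correlation). Leaving out replicate 1 at 2 DAP ended the call of the auxin (adjusted p = 0.0617), abscisic acid (0.0532), bZIP (0.0581) and tubulin (0.138) lists. Leaving out replicate 3 at 1 DAP ended that of the auxin (0.0762) and tubulin (0.196) lists, and the tubulin list also failed without replicate 1 at 0 DAP (0.0507) or replicate 2 at 2 DAP (0.0622). A pseudocount of 5 ended the call of the abscisic acid (0.0518) and small peptide (0.0997) lists, and leaving out all replicate 1 libraries that of the bZIP (0.0917) and tubulin (0.0748) lists, of which the tubulin list also failed by fry (0.103). Over all alternatives the adjusted p ran from 0.003 to 0.461 for abscisic acid, 0.00306 to 0.695 for small peptides, 0.002 to 0.328 for bZIP, 0.000558 to 0.773 for tubulin and 0.00329 to 0.559 for auxin genes, the highest in each being with an estimated correlation. In all limma called 6539 genes, 3162 higher and 3377 lower, and 10389 (5309 higher, 5080 lower) with the replicate block. The libraries did not overlap in 36.4% of genes, where chance gives 10%. The 11 lists that passed had adjusted p from 0.166 to 0.773 with an estimated correlation.

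From 2 to 3 DAP fewer genes changed. By camera the lists of ER protein folding and glycolysis rose and the MADS-box list fell, with few members called and none of the 3 passing with an estimated correlation (adjusted p = 0.166 to 0.269). HP1 (GRMZM2G016439) and HP3 (GRMZM2G451604), which relay cytokinin signals, rose from 98.6 ± 109 to 1380 ± 642 CPM (SD, n = 3) and from 22.1 to 419 CPM. The gene kin2 (GRMZM2G136838) rose from 5.21 ± 2.96 to 175 ± 50.1 CPM, CCD1 12.9-fold and the fructokinase gene frk2 6.72-fold. The auxin carrier PIN10a (GRMZM2G126260) fell from 19.4 to 0.905 CPM, ZMK1 47.3-fold, annexin (GRMZM2G132461) 43.4-fold, zmm29 14.9-fold and THX11 7.81-fold. Of 24 ER chaperones and disulfide isomerases 3 rose, PDIL1-2, PDIL1-1 and DER2.2, and 14 rose adjusted over the list alone (camera adjusted p = 6.01e-10, adjusted p = 0.166 with an estimated correlation). PDIL1-2 rose from 7.39 ± 3.02 to 31.4 ± 3.42 CPM. With the replicate block 9 rose and 1 fell, edgeR called 1 and DESeq2 5. Of 17 glycolytic genes 3 rose, eno1 (890 to 2230 CPM), GPC1 and phi1, and 9 rose adjusted over the list alone (5 by DESeq2, 10 with the replicate block), with a median log2 change of 0.82 (camera adjusted p = 8.06e-06, adjusted p = 0.252 with an estimated correlation). Of 28 MADS-box genes 4 fell, zmm29, zmm27, m24 and MADS18 (10 adjusted over the list alone, 9 by DESeq2, 8 with the replicate block; camera adjusted p = 1.54e-06, adjusted p = 0.269 with an estimated correlation). Of 6 aleurone genes 2 rose, Nkd1 (0.5 to 8.56 CPM) and vpp1 (3.76 to 23.2 CPM), and 3 rose adjusted over the list alone. The median log2 change was 0.62, or 1.61 with genes near 0 at their bounds (camera adjusted p = 3.75e-05, adjusted p = 0.0587 with an estimated correlation). The rise of vpp1 followed a fall from 1 to 2 DAP (limma adjusted p = 0.00018), after 20.5 CPM at 0 DAP and 19.9 CPM at 1 DAP. Of 14 heat shock genes 2 fell, HSP18 and hsp70-5 (3 adjusted over the list alone, 5 by DESeq2; camera adjusted p = 0.000365, adjusted p = 0.275 with an estimated correlation).

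Genes of the embryo-surrounding region, the endosperm next to the embryo, were near 0 at 2 DAP and at 0.249 to 2.38 CPM (means, n = 3) at 3 DAP for esr6, ESR3, esr1, esr2 and ae3. By limma 0 of the 5 were called, 1 rose adjusted over the list alone and 2 were at an unadjusted p below 0.05, while edgeR called 4 and DESeq2 called 5 higher. The list passed (camera adjusted p = 0.0333, adjusted p = 0.668 with an estimated correlation), but not without replicate 1 or 3 at 2 DAP (0.0542, 0.0504) or replicate 2 or 3 at 3 DAP (0.0512, 0.0509), nor with a pseudocount of 5 (0.42) or by fry (0.239). Over all alternatives its adjusted p ran from 0.00017 to 0.668. The median ribosomal gene fell by 0.45 on the log2 scale (camera adjusted p = 0.000362, adjusted p = 0.791 with an estimated correlation). By limma 0 of 39 ribosomal genes were called and 5 were lower at an unadjusted p below 0.05, edgeR and DESeq2 called 0, and the replicate block called 6 lower. Without replicate 1 at 3 DAP the ribosomal list did not pass (adjusted p = 0.436), nor by fry (0.441), in a range of 7.22e-11 to 0.791 over all alternatives.

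Several calls between 2 and 3 DAP were lost when 1 library was left out, in fits with fewer samples. Where the call was lost, the log2 change of PDIL1-1 was 1.23 to 1.73 (1.65 with all libraries). That of GPC1 was 1.42 to 1.66 (1.80) and that of phi1 0.84 to 0.94 (0.94). MADS18 was at -2.36 and -2.19 (-2.60) and hsp70-5 at -1.42 and -1.51 (-1.87). The adjusted p of PDIL1-1 lay between 0.0513 and 0.13 without any one of the 3 libraries at 3 DAP or replicates 1 and 2 at 2 DAP. That of GPC1 lay between 0.0739 and 0.0908 without replicate 1 or 2 at 2 DAP or replicate 3 at 3 DAP, and that of phi1 between 0.112 and 0.143 without those libraries or replicate 1 at 3 DAP. MADS18 lost its call without replicate 2 at 2 DAP (0.0613) or replicate 1 at 3 DAP (0.0562), and hsp70-5 without replicate 3 at 2 DAP (0.072) or replicate 1 at 3 DAP (0.0877). Without all replicate 1 libraries PDIL1-1 (0.0739), MADS18 (0.0722), hsp70-5 (0.0698) and phi1 (0.16) were not called. With the compared groups alone HP1 (0.0641), HP3 (0.0717), eno1 (0.0952), GPC1 (0.117), PDIL1-1 (0.161), hsp70-5 (0.137) and phi1 (0.0987) were not called, and by edgeR HP3 (0.0812), PDIL1-1 (0.0718) and DER2.2 (0.0574) were not. The lowest adjusted p over all alternatives of these genes, DER2.2 aside, ran from 6.86e-09 for eno1 to 0.0013 for phi1. In all limma called 837 genes, 600 higher and 237 lower. With the replicate block 2424 were called, 1491 higher and 933 lower, and DESeq2 called 2088. The count fell to 389, 404, 473 or 360 without replicate 1 or 2 at 2 DAP or replicate 1 or 3 at 3 DAP, in that order. Of the called genes 71.7% were higher, against 61.5% with the block, 60.8% by edgeR and 61.4% by DESeq2. The libraries did not overlap in 21.6% of genes, where chance gives 10%.

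From 3 to 4 DAP, genes of the basal endosperm transfer layer and of the embryo-surrounding region rose from near 0. The transfer-layer gene meg2 (GRMZM2G088896) rose from 0.117 ± 0.126 to 893 ± 511 CPM (SD, n = 3), and its other model GRMZM2G094054, which may share reads with it, from 0.022 to 205 CPM. The secreted peptide genes betl2 (GRMZM2G152655), BETL1 (GRMZM2G082785) and bap-3a (GRMZM2G133382) rose from 0.055, 0.044 and 0.0238 CPM to 215 ± 133, 71.8 ± 46.5 and 71.4 ± 39.9 CPM. By DESeq2 the adjusted p of BETL1 was 0.0616, the highest over its alternatives, of which the lowest was 7.95e-12. PPDK2 (GRMZM2G097457) rose 469.6-fold and fl3 (GRMZM2G006585) 376.5-fold. Among the genes that fell, invertase1 went from 14.7 to 1.42 CPM and HSP60-1 from 709 to 235 CPM. Of 18 transfer-layer genes 15 rose and 0 fell (15 and 2 adjusted over the list alone), with a median log2 change of 4.63, or 9.74 with genes near 0 at their bounds. By edgeR 14 rose and by DESeq2 12 rose and 1 fell, with tcrr-1 not called by either (adjusted p = 0.0878 and 0.318) and bap1-b not by DESeq2 (0.249). This list passed both ways (camera adjusted p = 1.27e-52, adjusted p = 0.0205 with an estimated correlation), though with the replicate block the latter was 0.106. The members that did not rise were EBE-1, EBE-2 and MRP1. Of the 20 small secreted peptides, which share members with this list, 14 rose by either adjustment (camera adjusted p = 4.05e-43, adjusted p = 0.017 with an estimated correlation, or 0.068 with the block). Of 5 embryo-surrounding genes 4 rose by either adjustment: esr1 from 0.781 ± 0.370 to 77.3 ± 50.4 CPM, esr6 84.8-fold, esr2 20.2-fold and ESR3 (camera adjusted p = 1.42e-11, adjusted p = 0.124 with an estimated correlation).

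The aleurone, starch and auxin lists rose as well between 3 and 4 DAP by camera, though not with an estimated correlation (adjusted p = 0.0587 to 0.252). Of 6 aleurone genes 3 rose by either adjustment: Nkd1 from 8.56 ± 3.14 to 37.0 ± 4.40 CPM (SD, n = 3), Nkd2 11.03-fold and vpp1 2.53-fold (camera adjusted p = 3.31e-05, adjusted p = 0.0587 with an estimated correlation). Of 21 starch genes 7 rose (9 and 1 lower adjusted over the list alone, 4 by edgeR), including du1 from 36.9 to 112 CPM and AGP2 (GRMZM2G027955) from 0.79 to 28.2 CPM (camera adjusted p = 0.000119, adjusted p = 0.119 with an estimated correlation). Of 40 auxin genes 4 rose (8 adjusted over the list alone, 7 by DESeq2, 9 with the replicate block): yuc, ARF11, ARF16 and ARF28 (camera adjusted p = 2.42e-05, adjusted p = 0.252 with an estimated correlation). The synthesis gene yuc (GRMZM2G091819) had 1 read at 3 DAP and 2767 at 4 DAP, a ratio of pooled reads of 1963 with a counting interval of 352 to 77560 (1166 as the ratio of mean CPM), and ARF11 and ARF16 rose 9.19-fold and 4.77-fold. Heat shock, ribosomal, replication and translation lists fell by camera but not with an estimated correlation (adjusted p = 0.269 to 0.668). Of 14 heat shock genes 1, HSP60-1, fell (4 adjusted over the list alone, 4 by edgeR, 6 by DESeq2, 5 with the replicate block; camera adjusted p = 0.000323, adjusted p = 0.269 with an estimated correlation). The median ribosomal gene fell by 0.72 on the log2 scale (camera adjusted p = 9.69e-08, adjusted p = 0.668 with an estimated correlation). By limma 0 of 39 ribosomal genes were called and 8 were lower at an unadjusted p below 0.05, edgeR called 0, DESeq2 called 1, rpl10, lower, and the replicate block called 28 lower. By fry the ribosomal list did not pass (0.217), and its adjusted p ran from 6.53e-21 to 0.668 over all alternatives. The replication and translation lists (camera adjusted p = 0.000512 and 0.00187, adjusted p = 0.331 and 0.6 with an estimated correlation) had 0 called members by limma or edgeR (0 and 1 lower adjusted over the list alone), 1 lower each by DESeq2 (orc3 and eif7), 6 and 2 lower at an unadjusted p below 0.05, and 4 each lower with the block. They did not pass without replicate 1 at 3 DAP (replication, 0.0792) or replicate 1 at 4 DAP (translation, 0.0551). Nor did they pass without all replicate 1 libraries (replication, 0.148) or after quantile normalization or by fry (translation, 0.406 and 0.0925). The adjusted p over all alternatives ran from 2.39e-06 to 0.331 and from 8.7e-05 to 0.6.

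Calls of genes changed less strongly between 3 and 4 DAP were also lost when 1 library was left out, in fits with fewer samples. Where the call was lost, the log2 change of CAD2 was -2.67 to -2.03 (-2.61 with all libraries) and that of 4CL -2.47 to -1.79 (-2.29). That of mha2 was -1.35 to -1.29 (-1.41) and that of vpp1 1.05 to 1.43 (1.35). CAD2 fell 6.09-fold, 4CL 7.26-fold and mha2 2.67-fold, but all 3 failed without any one of replicates 2 and 3 at 3 DAP or 1 and 2 at 4 DAP. Their adjusted p then lay between 0.087 and 0.15, 0.0773 and 0.182, and 0.0777 and 0.112. By edgeR, 4CL (0.178), CAD2 (0.0588) and Nkd1 (0.117) were not called, and in a fit of the compared groups alone 4CL (0.117), CAD2 (0.095), esr2 (0.067), esr6 (0.0522) and vpp1 (0.0799) were not. 4CL also failed with a pseudocount of 0.25 (0.0919) and mha2 without all replicate 1 libraries (0.0528). Over all alternatives the adjusted p of Nkd1 ran from 1.73e-06, that of esr2 from 2.81e-07 and that of esr6 from 3.77e-08 to the highest value given here. The rise of vpp1 failed without replicate 2 at 3 DAP (0.171) or replicate 1, 2 or 3 at 4 DAP (0.115, 0.0929, 0.0528). In all limma called 792 genes, 532 higher and 260 lower. The count fell to 323, 454 or 344 without replicate 2 at 3 DAP or replicate 1 or 2 at 4 DAP, and rose to 1213 without the 2 shallowest libraries and 1226 without all replicate 1 libraries. With the replicate block 2739 genes were called, 1150 higher and 1589 lower, so that 67.2% of called genes were higher without the block and 42.0% with it; DESeq2 gave 54.8% of 1574. The libraries did not overlap in 22.9% of genes, where chance gives 10%.

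**Figure D2:**
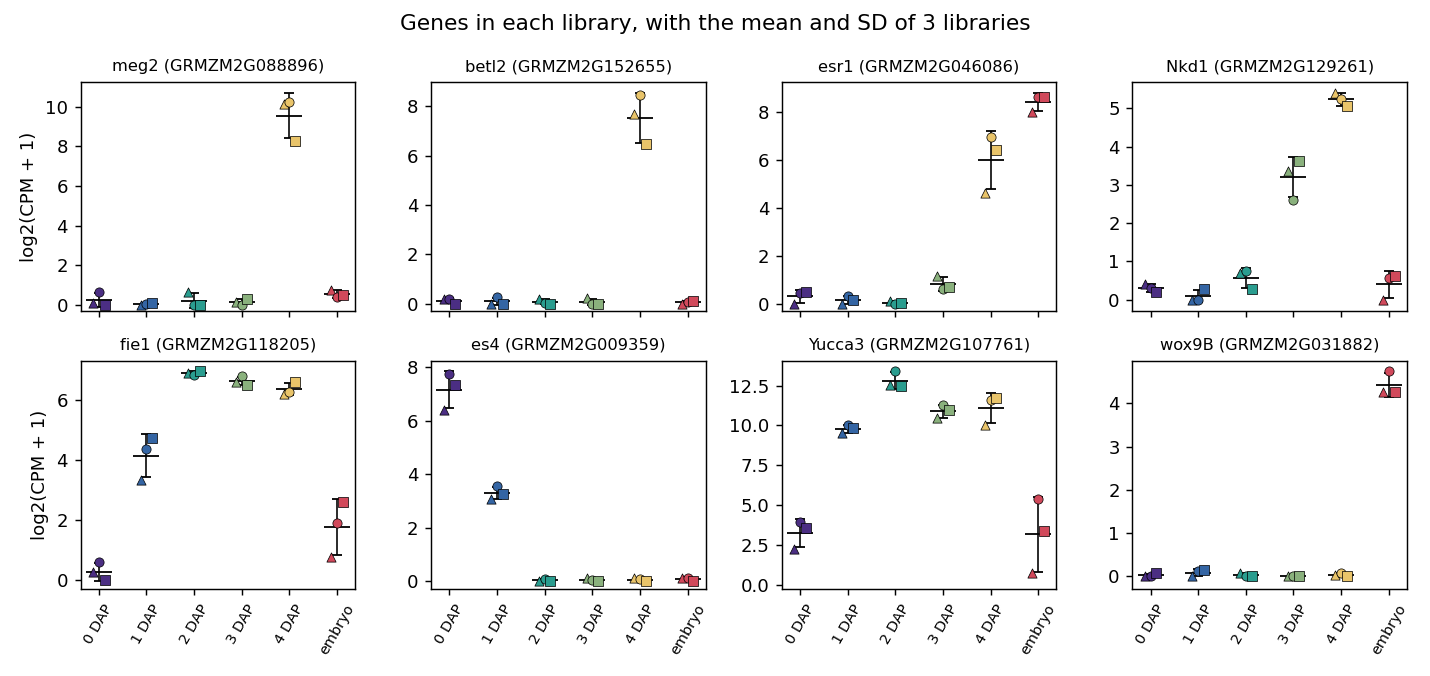
Log2(CPM + 1) per library for meg2 (GRMZM2G088896), betl2, esr1, Nkd1, fie1, es4, Yucca3 and wox9B in the 6 groups, with the mean and SD of each group of 3. The transfer-layer genes are near 0 until 3 DAP and reach 893 (meg2) and 215 CPM (betl2) at 4 DAP, fie1 reaches 120 CPM at 2 DAP, and wox9B is at 20.8 CPM in the embryo.

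The endpoints, 4 DAP endosperm against the 0 DAP central cell, differed most among the endosperm comparisons. Against 0 DAP, meg2 (GRMZM2G088896) was 4106-fold higher at 893 ± 511 CPM (SD, n = 3), betl2 2461-fold, Yucca3 260.6-fold at 2495 ± 1281 CPM, and HP1 88.4-fold at 721 ± 499 CPM. The embryo-sac genes es4, es2 and es1 were 3466-fold, 3395-fold and 3261-fold lower. HRGP fell from 268 to 0.382 CPM, the lipid transfer protein gene PLTP from 91.2 to 0.165 CPM, and GRMZM2G039942 (ae1) from 859 ± 479 to 3.53 ± 2.82 CPM. Of 28 MADS-box genes 20 fell, such as zag2 (79.7 to 2.02 CPM), zmm29 and MADS18, and 1 rose, MADS42 (21 and 1 adjusted over the list alone), with a median log2 change of -1.51, or -4.04 with genes near 0 at their bounds (camera adjusted p = 3.69e-07, adjusted p = 0.268 with an estimated correlation). Of 12 histone genes 11 rose (12 adjusted over the list alone), with his1 at 76.8 ± 0.720 against 8.58 ± 3.67 CPM (camera adjusted p = 4.33e-05, adjusted p = 0.549 with an estimated correlation), and of 14 mitotic regulators 11 rose (camera adjusted p = 0.000102, adjusted p = 0.461 with an estimated correlation). Of 18 transfer-layer genes 15 rose and 2 fell, EBE-1 and MRP1, the latter from 35.7 ± 8.67 to 0.0708 ± 0.101 CPM (camera adjusted p = 8.32e-14, adjusted p = 0.252 with an estimated correlation). All 5 embryo-surrounding genes rose, esr1, esr2, esr6, ESR3 and ae3, with a median log2 change of 4.06, or 8.10 with genes near 0 at their bounds (camera adjusted p = 5.54e-05, adjusted p = 0.325 with an estimated correlation). Of 6 aleurone genes 5 rose, Nkd1, Nkd2, dek1, vpp1 and cr4 (camera adjusted p = 0.00139, adjusted p = 0.143 with an estimated correlation).

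Other lists moved in both directions from 0 to 4 DAP. Of 14 heat shock genes 9 fell (9 and 1 higher adjusted over the list alone), with HSP18 at 0.0195 against 16.3 CPM (means, n = 3; camera adjusted p = 0.0149, adjusted p = 0.516 with an estimated correlation). Of 19 cell-death genes 8 fell, including Atg8a from 96.1 to 14.9 CPM (camera adjusted p = 0.0253, adjusted p = 0.549 with an estimated correlation). Of 7 embryo-sac genes 6 fell, and of 4 gibberellin genes 3, d3, CPPS2 and an1 (camera adjusted p = 3.57e-05 and 0.0217, adjusted p = 0.252 for both with an estimated correlation). Of 20 small secreted peptides 14 rose and 4 fell (14 and 5 adjusted over the list alone): es1, es2, es4 and PLTP (camera adjusted p = 1.61e-05, adjusted p = 0.344 with an estimated correlation). Of 14 kinesins and phragmoplast proteins 8 rose, and kin1 and ktn2 fell (camera adjusted p = 0.00229, adjusted p = 0.269 with an estimated correlation). Of 11 WRKY genes 4 rose: WRKY3, WRKY116 and the WRKY1 models GRMZM2G398506 and GRMZM2G018487 (camera adjusted p = 0.033, adjusted p = 0.268 with an estimated correlation). Of 21 starch genes 10 fell and 2, du1 and sus2, rose (camera adjusted p = 0.0431, adjusted p = 0.331 with an estimated correlation). Of 12 genes of the nucellus and seed coat, which are maternal tissues, 6 fell and 1 rose by limma under either adjustment, by edgeR and by DESeq2, and 6 of the 9 that changed over the time course were highest at 0 DAP. As a list they did not pass (camera adjusted p = 0.09807, adjusted p = 0.7391 with an estimated correlation). The rise of sus2 was not called by edgeR (0.104) or DESeq2 (0.0729), nor the fall of kin1 by DESeq2 (0.183). The starch list did not pass with the replicate block (0.0648) or without replicate 1 at 0 DAP (0.0668) or replicate 3 at 4 DAP (0.097). The cell-death list failed without replicate 2 at 0 DAP (0.0563) or replicate 1 at 4 DAP (0.0551), and the WRKY list without replicate 1 or 2 at 0 DAP (0.0519, 0.0572). Without all replicate 1 libraries the starch (0.0539), heat shock (0.0561) and WRKY (0.0518) lists did not pass, and without the 2 shallowest libraries the starch list did not (0.0525). Over all alternatives the adjusted p of the starch list ran from 4.19e-05 to 0.331, that of heat shock from 0.000192 to 0.516 and that of WRKY from 8.23e-05 to 0.268. In all limma called 11823 genes, 5564 higher and 6259 lower, and 15357 with the replicate block. The libraries did not overlap in 50.3% of genes, where chance gives 10%. The 14 lists that passed had adjusted p from 0.143 to 0.549 with an estimated correlation.

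**Figure D3:**
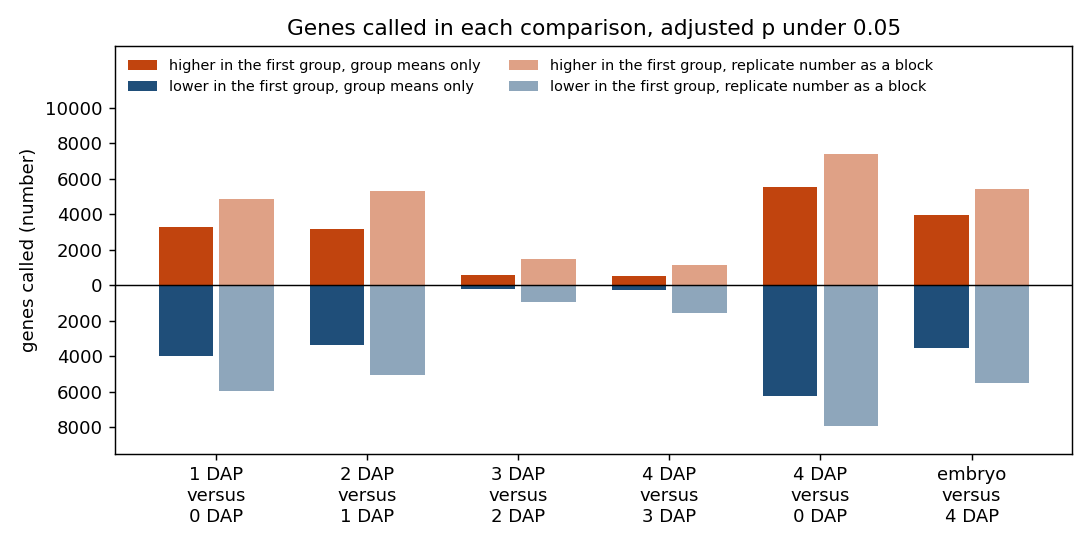
Number of genes called higher and lower in each comparison by limma, with group means only and with the replicate number as a block, bars starting at 0. The block adds calls in all 6 comparisons, from 792 to 2739 between 3 and 4 DAP.

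Over the 5 endosperm stages, 16866 of 31783 genes (53.1%) changed by the limma F test, and 21503 with the replicate block. Among them 5972 were highest at 0 DAP, 2482 at 1 DAP, 3448 at 2 DAP, 1663 at 3 DAP and 3301 at 4 DAP. Genes higher at 1 stage than at each of the other 4 numbered 2268 at 0 DAP, 524 at 1 DAP, 42 at 2 DAP, 1 at 3 DAP and 341 at 4 DAP, 3176 in total (5058 with the block, of which 308, 41 and 573 at 2, 3 and 4 DAP). The 1 gene at 3 DAP, GRMZM2G152947, chosen after its values were seen, had 24.85 ± 5.22 CPM (SD, n = 3) there and 9.66, 5.17, 10.21 and 12.39 CPM at 0, 1, 2 and 4 DAP. That gene was not called without replicate 2 at 3 DAP or any 1 library at 4 DAP, when the count was 0; it was 2 without replicate 1 at 1 DAP, 3 without replicate 3 at 2 DAP and 6 without replicate 1 at 3 DAP. The count at 2 DAP fell to 19 or 27 without replicate 2 or 3 at 2 DAP and to 27 or 22 without replicate 1 or 3 at 3 DAP. The count at 4 DAP fell to 210 without replicate 2 at 3 DAP and to 209 without replicate 2 at 4 DAP.

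Shares of the gene lists that changed over the time course are to be read against the 53.1% of all genes, and the MYB, fatty acid, heat stress factor, embryo regulator and bZIP lists lay under it. All 18 transfer-layer, 12 histone, 7 embryo-sac, 5 embryo-surrounding, 5 photosynthesis, 4 gibberellin and 3 ethylene genes changed by the limma F test. Changes were also called for 19 of 20 small secreted peptides, of which 14 were highest at 4 DAP, and for 12 of 13 translation factors. Of the ribosomal genes 26 of 39 changed, 22 of them highest at 2 DAP, and of the MADS-box genes 22 of 28, 18 of them highest at 0 DAP. Of the ER chaperones 19 of 24 changed, 11 of them highest at 3 DAP. Further, 19 of 21 starch, 29 of 33 cell wall, 14 of 17 glycolytic, 13 of 14 heat shock, 11 of 14 mitotic, 9 of 14 kinesin and phragmoplast, 10 of 17 replication and 15 of 20 tubulin and actin genes changed. So did 26 of 40 auxin, 15 of 27 cytokinin, 15 of 20 abscisic acid, 21 of 29 defence, 11 of 19 cell-death, 9 of 12 nucellus, 6 of 9 sugar transport, 6 of 9 storage protein, 5 of 12 fatty acid, 3 of 5 G1/S and 5 of 6 aleurone genes. Among regulators, 10 of 11 Polycomb and imprinted genes changed, 13 of 19 of DNA methylation and small RNA, 17 of 27 homeobox, 15 of 30 bZIP, 10 of 25 MYB, 8 of 11 WRKY, 6 of 11 NAC, 6 of 11 NF-Y, 11 of 18 AP2/ERF and 3 of 8 heat stress factors, and 7 of 15 embryo regulators. The lists that passed camera in none of the 6 comparisons had as their lowest adjusted p 0.0531 for NAC and for Polycomb and imprinted genes, 0.054 for heat stress factors, 0.0594 for fatty acids, 0.0611 for nucellus and 0.0617 for AP2/ERF. That value was 0.168 for ethylene, 0.17 for DNA methylation and small RNA, 0.176 for MYB, 0.278 for storage proteins, 0.292 for G1/S, 0.311 for cytokinin and 0.344 for photosynthesis. Polycomb genes moved apart: fie1 rose from 0.242 ± 0.262 CPM (SD, n = 3) at 0 DAP to 120 ± 5.05 CPM at 2 DAP, while fie2 was between 38.4 and 55.6 CPM and was not called. From 0 to 1 DAP mez2 fell from 48.1 to 15.6 CPM, vef101 from 95.9 to 42.7 CPM and mez3 from 17.8 to 6.82 CPM (limma adjusted p = 0.000664, 0.00181 and 0.016). From 3 to 4 DAP nfc104 fell from 97.3 to 40.6 CPM and mez2 rose from 13.1 to 31.4 CPM (limma adjusted p = 0.00233 and 0.0344).

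**Figure D4:**
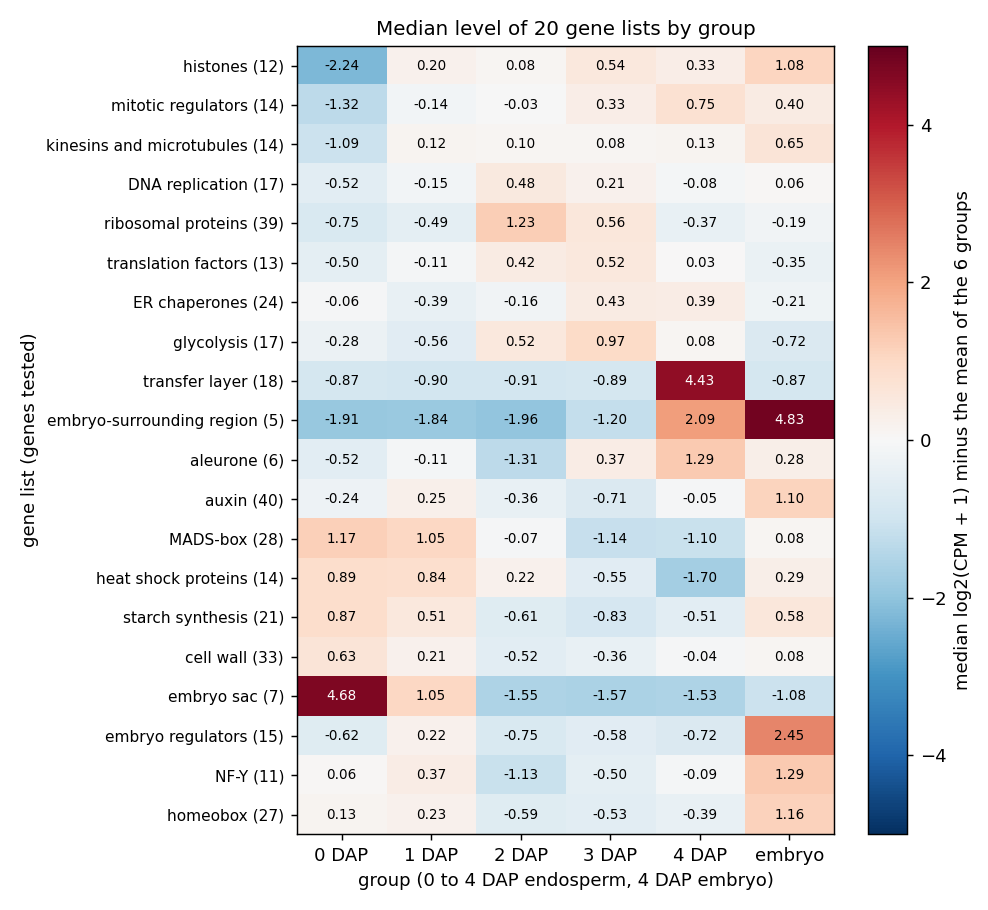
Median log2(CPM + 1) of the members of 20 gene lists in each of the 6 groups, minus the mean of the 6 group medians, as colours on a labelled scale. The transfer-layer list is at 4.43 at 4 DAP, the embryo-sac list at 4.68 at 0 DAP, the ribosomal list at 1.23 at 2 DAP and the embryo-surrounding list at 4.83 in the embryo.

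At 4 DAP the embryo and the endosperm differed in regulators and in tissue genes. CER1 (GRMZM2G099097) was 5017-fold higher in the embryo at 813 ± 238 CPM (SD, n = 3). HRGP, gst23 and TRAF25 were higher there at 140, 103 and 73.6 CPM against 0.382, 0.0594 and 0.088 CPM. The gene hscf1 (GRMZM2G139082) had 166 CPM in the embryo and 2 reads in the endosperm, a ratio of pooled reads of 25760 with a counting interval of 7130 to 212700 (18360 as the ratio of mean CPM). In the endosperm, meg2 was 1823-fold and betl2 5006-fold higher, Yucca3 148.6-fold higher, and BETL1 had 0 reads in the embryo, at least 3262-fold lower there. Of 15 embryo regulators 6 were higher in the embryo, among them wox9B (20.8 ± 4.35 against 0.0239 CPM), lec1 (17.7 ± 10.5 against 0.0351 CPM), vp1 (29.9 ± 14.5 against 0.285 CPM) and wox9C, with 16.2 ± 7.33 CPM and 0 reads in the endosperm, at least 1704-fold higher. The 1 lower was serk1 (camera adjusted p = 0.000354, adjusted p = 0.216 with an estimated correlation). Of 11 NF-Y genes, which share lec1 with that list, 6 were higher and 0 lower, with NF-YA13 at 42.3 ± 11.3 CPM and 0 reads in the endosperm, at least 4080-fold higher, and NF-YA4 (GRMZM5G853836) 4.39-fold higher. By edgeR the adjusted p of NF-YA4 was 0.0753, the highest over its alternatives, of which the lowest was 6.34e-05. Their median log2 difference was 1.99, or 2.28 with genes near 0 at their bounds. The NF-Y list passed both ways (camera adjusted p = 1.43e-05, adjusted p = 0.0261 with an estimated correlation), though the latter was 0.0899 with the replicate block. Of 27 homeobox genes 11 were higher, such as ocl3 12.7-fold, and 1, homeobox1, lower (camera adjusted p = 0.00079, adjusted p = 0.268 with an estimated correlation). The higher genes include wox9B and wox9C of the embryo regulators, so these 2 lists are not separate results.

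By camera the transfer-layer, glycolytic and sugar transport lists were lower in the embryo than in the endosperm, and the heat shock list was higher, none of them with an estimated correlation (adjusted p = 0.0949 to 0.268). Of 18 transfer-layer genes 17 were lower, with a median log2 difference of -4.89, or -9.56 with genes near 0 at their bounds (camera adjusted p = 3.28e-27, adjusted p = 0.0949 with an estimated correlation). Of 17 glycolytic genes 9 were lower (11 adjusted over the list alone, 14 with the replicate block), with eno1 at 829 ± 37.9 against 3907 ± 366 CPM (SD, n = 3), gpc4 6.71-fold and phi1 5.73-fold lower (camera adjusted p = 9.76e-06, adjusted p = 0.252 with an estimated correlation). Of 9 sugar transport genes 4 were lower, mn1, sut1, ERD6 and MST1 (5 adjusted over the list alone; camera adjusted p = 0.00611, adjusted p = 0.268 with an estimated correlation). By edgeR MST1 (0.055) was not called, and mn1 is also a member of the transfer-layer list. Of 14 heat shock genes 8 were higher, with hsp22 at 90.7 against 3.92 CPM, hsp70-5 32.9-fold and HSP90-1 3.09-fold higher (camera adjusted p = 0.000201, adjusted p = 0.268 with an estimated correlation). Of 5 embryo-surrounding genes, named for the endosperm around the embryo, 4 were called higher in the embryo libraries: esr1 at 350 ± 82.8 against 77.3 ± 50.4 CPM, esr2 at 184, esr6 at 123 and ESR3 at 67.6 CPM. The other, ae3, was at 16.5 ± 11.6 against 6.48 ± 5.27 CPM and was not called (adjusted p = 0.136), except when adjusted over the list alone (camera adjusted p = 0.000872, adjusted p = 0.449 with an estimated correlation). By edgeR esr2 (0.0625) was not called either, and by DESeq2 neither esr1 (0.0935) nor esr2 (0.101), so that edgeR called 3 and DESeq2 2 of the 5. Of 20 small secreted peptides 7 were higher and 10 lower by either adjustment (camera adjusted p = 0.00272, adjusted p = 0.589 with an estimated correlation, 0.0866 without all replicate 1 libraries, and 6.69e-06 at the lowest). Of 20 abscisic acid genes 6 were higher, including vp1, and 3 lower, SnRK2.11, SnRK2.7 and PYL8 (9 and 3 adjusted over the list alone), of which PYL8 was not called by edgeR (0.056), and DESeq2 called 10 higher. That list passed at camera adjusted p = 0.0498 (adjusted p = 0.555 with an estimated correlation) and was at 0.0648 with the replicate block, 0.107 without all replicate 1 libraries, 0.065 without the 2 shallowest and 0.0899 with a pseudocount of 5, and 0.000422 at the lowest over all alternatives. Leaving out replicate 2 or 3 of the embryo, replicate 1 or 2 at 0 DAP, any of the 3 libraries at 1 DAP, replicate 1 at 2 DAP or replicate 1 at 4 DAP gave the abscisic acid list an adjusted p between 0.05 and 0.0734. The Polycomb gene fie1 was at 2.88 ± 2.23 CPM in the embryo against 82.1 ± 12.1 CPM in the endosperm, whereas fie2 was higher in the embryo, at 84.0 ± 16.5 against 38.4 ± 2.44 CPM. In all limma called 7475 genes, 3951 higher and 3524 lower in the embryo, and 10974 (5445 and 5529) with the replicate block. The libraries did not overlap in 38.9% of genes, where chance gives 10%.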

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

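The tests without the 2 shallowest libraries, without all replicate 1 libraries, and by edgeR with a replicate block, and those of list members outside the rule for named genes by edgeR, DESeq2 and the block, were chosen only after the results were seen. No named gene and no list reversed, but the balance of calls did. Between 3 and 4 DAP 67.2% of called genes were higher, against 42.0% with the block, and from 0 to 1 DAP 45.1%, against 56.4% by edgeR and 51.1% by DESeq2. Smaller turns were from 48.4% to 51.1% with the block for 2 against 1 DAP, from 52.9% to 49.6% with it for the embryo, and from 47.1% to 50.7% after quantile normalization for 4 against 0 DAP. The 131 results for named genes kept their direction in all 2750 values under an alternative, 2678 of them past the threshold, and 109 results passed under every alternative. Named genes were chosen with 3 libraries all above the other 3, so most of these alternatives could not turn their direction. The 63 list results kept their direction in all 1638 values, 1519 of them past the threshold, and 3 passed under every alternative taken singly. With an estimated correlation combined with the block, or without the 2 shallowest or all replicate 1 libraries, 0 lists passed, against 63, 3 with an estimated correlation alone, and 69, 68 and 67 without it. Quantile normalization went the other way, with 70 lists, and 5 when combined with an estimated correlation. Called list members named outside these 131 results were compared with edgeR and DESeq2, where 0 turned direction, and with the block, where 0 lost the call. Calls were lost by both tools, however. Of all called list members edgeR also called 155 of 199 for 1 against 0 DAP, 192 of 217 for 2 against 1 DAP and 28 of 39 for 3 against 2 DAP. It called 43 of 56 for 4 against 3 DAP, 318 of 338 for 4 against 0 DAP and 211 of 239 for the embryo. DESeq2 called 176, 205, 37, 49, 326 and 224 of them in the same order. The replicate block ended the call of 0 of the named genes and of 3 lists, the bZIP list from 0 to 1 DAP, the starch list from 0 to 4 DAP and the abscisic acid list in the embryo, and changed no other call among them. All genes called without the block in the 6 comparisons were also called with it. With the block the counts that moved by over 1.5 times were 10389 for 2 against 1 DAP, 2424 for 3 against 2 DAP, 2739 for 4 against 3 DAP, and 5058 stage-enriched genes, with 308 at 2 DAP, 41 at 3 DAP and 573 at 4 DAP. With array weights they were 11424 for 1 against 0 DAP, 2235 for 3 against 2 DAP, 4295 for 4 against 3 DAP, and 5717 stage-enriched genes, with 3608, 987, 187, 38 and 897 at 0 to 4 DAP. By edgeR they were 1907 stage-enriched genes, with 1324 at 0 DAP, 22 at 2 DAP and 204 at 4 DAP. By edgeR with the block they were 9999, 2833 and 2484 for the steps from 1 to 4 DAP, and 404 and 16 stage-enriched genes at 2 and 3 DAP. DESeq2 gave 2088 for 3 against 2 DAP and 1574 for 4 against 3 DAP. A fit of the compared groups alone, which has fewer samples, gave 4305 for 1 against 0 DAP, 366 and 393 for the last 2 steps, and 4 stage-enriched genes at 3 DAP. A 2-fold minimum, which can only lower a count, left 4542 for 1 against 0 DAP, 4043 for 2 against 1 DAP, 7849 for 4 against 0 DAP and 4941 for the embryo. A filter of 5 CPM, with fewer genes tested, gave 4843 for the embryo and 1996 stage-enriched genes, with 1445, 297, 3 and 218 at 0, 1, 3 and 4 DAP. The few stage-enriched genes of 2 and 3 DAP moved most easily: 25 at 2 DAP with a pseudocount of 0.25, 8 at 3 DAP with 5, and 2 at 3 DAP with no filter or after quantile normalization. Without the 2 shallowest libraries 1213 genes were called for 4 against 3 DAP, with 65 and 6 stage-enriched genes at 2 and 3 DAP, and without all replicate 1 libraries 1226 and 3 at 3 DAP. Of the 252 list tests 63 passed; with an estimated correlation 3 did. By fry 98 passed, but fry asks whether members move one way, not whether they differ from other genes, so this is no count of the same result. Where no construction is named, the cause was not tested.

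Leaving out 1 library at a time gave 5489 to 6761 genes for 1 against 0 DAP, 4652 to 5621 for 2 against 1 DAP, 360 to 699 for 3 against 2 DAP, 323 to 671 for 4 against 3 DAP, 9618 to 10836 for 4 against 0 DAP and 5706 to 7176 for the embryo. These fits have fewer samples. The time course gave 15030 to 17203 genes, the stage-enriched genes 2527 to 3026, with 1731 to 2171, 400 to 594, 19 to 42, 0 to 6 and 209 to 365 at 0 to 4 DAP, and 60 to 70 lists passed. Depth limits genes near 0: 3 reads were 0.335 CPM in replicate 1 at 1 DAP and 0.0263 CPM in replicate 1 at 4 DAP.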

Other observations

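All tests of explanations given here were chosen only after the result was seen, except the counts of other groupings, which were fixed before the data were examined, those within replicate numbers aside. Of 19 genes of DNA methylation and small RNA, 5 rose and 2 fell between 0 and 4 DAP, and the list did not pass (camera adjusted p = 0.1697, adjusted p = 0.71 with an estimated correlation). Among them, picked here after their values were seen, met2 rose from 9.81 to 137 CPM and the dmt101 model GRMZM2G334041 from 65.6 to 287 CPM (means, n = 3; limma adjusted p = 2.78e-09 and 9.7e-05), while the other dmt101 model, GRMZM2G333997, was not called (3.06 and 4.37 CPM, adjusted p = 0.331). The 2 that fell were rmr2 and mop1, of the small RNA pathway, from 29.9 to 2.83 CPM and from 14.4 to 4.62 CPM (adjusted p = 5.54e-08 and 4.28e-05). The embryo-sac genes EBE-1 and EBE-2 were lower at 1 DAP and rose at 2 DAP, though the fall of EBE-2 was not called by edgeR (adjusted p = 0.0561). EBE-2 had 378.5 ± 215.5, 114.9 ± 25.04 and 799.6 ± 356.6 CPM (SD, n = 3) at 0, 1 and 2 DAP (limma adjusted p = 0.0471 for the fall and 0.00239 for the rise), 198 ± 81.8 CPM at 4 DAP, and 7.51 ± 5.63 CPM in the embryo.

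Of 40 auxin genes 16 were higher and 9 lower in the embryo than in the endosperm at 4 DAP, and of 27 cytokinin genes 5 and 4, and neither list passed (camera adjusted p = 0.06105 and 0.5565). The lower cytokinin genes HP3, RR6 and crr2 were not called by edgeR (adjusted p = 0.0914, 0.129 and 0.202) or DESeq2 (0.087, 0.081 and 0.135). The higher HK1 was not called by edgeR (0.085). The following were picked after their values were seen. The auxin response factors ARF23, ARF4 and ARF2 had 40.3, 11.6 and 21.5 CPM in the embryo and 1.065, 0.035 and 1.422 CPM in the endosperm (means, n = 3; limma adjusted p = 3.66e-09, 3.65e-09 and 1.29e-08). The auxin carrier PIN1a was at 8.39 CPM in the embryo and listed at 0 in the endosperm (adjusted p = 9.31e-10). The cytokinin genes abph1 and CKX10 were at 18.7 and 12.2 CPM in the embryo against 0 and 0.014 CPM (adjusted p = 1.83e-08 and 5.58e-10), whereas HP1 was lower there, at 69.7 against 721 CPM (adjusted p = 0.00429).

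How many genes are called when the libraries are regrouped at random was counted. For each comparison, 1 of the 10 splits of its 6 libraries, the real one, called as many genes, and 10 splits are too few for a share under 0.05. The real counts and the highest of the other splits were 7276 and 23 for 1 against 0 DAP, 6539 and 0 for 2 against 1 DAP, 837 and 3 for 3 against 2 DAP, 792 and 2 for 4 against 3 DAP, 11823 and 0 for 4 against 0 DAP, and 7475 and 1 for the embryo. The highest count was 0 among the other splits that part all 3 replicate numbers. For the time course, 1 of 100 groupings, the real one, called as many as 16866 genes, the highest other being 3431. For stage-enriched genes 1 of 100 reached 3176, the highest other being 262. That is the smallest share that 100 groupings can give, so it argues against chance for both without excluding it. Regrouping also leaves the stage differences in the spread, which lowers the other counts. Those groupings ignore the replicate number. In 99 others, with the stages exchanged within each number so that every pair is parted, the highest counts were 4735 and 1811.

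Libraries of replicate 1 deviated from their groups together, and 12236 genes were called between replicate 1 and the other libraries (5434 higher, 6802 lower), against 1427 for replicate 2 and 4745 for replicate 3. Depth is argued against, since replicate 1 deviated in the same direction in 6 of 6 groups although it was the shallowest library in 2 and the deepest in 2. Scaling as the whole cause is argued against, since genes moved both ways and 85.02% or more of those called in each direction were called in that direction after quantile normalization, with a lowest correlation between replicate 1 libraries of 0.4794. Replicate number accounted for 49.96% of the spread within groups, where 50 random renumberings gave at most 33.16%. A harvest or library batch shared by same-numbered libraries could produce this and stays open, since the labels give no batch, and no biological explanation was tested.

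Of 5 genes of the embryo-surrounding region (ESR), 4 were called higher in the embryo libraries than in the endosperm by limma, 3 by edgeR and 2 by DESeq2, and the ratios ran from 2.541 (ae3, not called, adjusted p = 0.136) to 5.955. Endosperm of average composition in the embryo capture is argued against, since the median of 14 transfer-layer genes in the embryo was 0.06676% of its endosperm level (10.02% at the highest), and fie1 was at 3.508%. ESR cells adhering to the embryo might give the pattern, and would raise the ESR genes alike. Their embryo to endosperm ratios differed by 2.343 times between the highest and the lowest, which does not decide between adhering cells and expression in the embryo itself, so these cannot be told apart without cells sorted by position.

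Transcripts of es1, es2 and es4 were still measured at 1 DAP, at 4.553% to 7.343% of their 0 DAP level, where the median of 1582 genes at 100 CPM or more at 0 DAP kept 82.08%. Unfertilized central cells in the 1 DAP capture would set a lowest share that abundant genes keep. With the highest 1 DAP library set against the lowest 0 DAP library, 3 genes (d3, GRMZM2G021051 and AC199577.4_FG004, named after their values were seen) kept less than the lowest embryo-sac share, and 5 did by their means, where 10 by the first measure would have argued against this explanation. Transcripts that outlast fertilization may also remain, with at most 0.5081% of the 1 DAP level left at 2 DAP. For these 3 genes, such as d3 at 282.2 CPM at 0 DAP and 2.823 CPM at 1 DAP, the values argue against unfertilized cells as the whole source. They are 3 of 1582 genes, fewer than the 10 set, so a part from such cells stays open. Such a part and lasting transcripts cannot be told apart, and a difference between the stages themselves was not tested.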
